A study of Mus musculus with 2 samples.

How the data were processed

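The series holds 2 single-cell RNA libraries made on the 10x Genomics droplet system from sorted cells of mouse hindlimb muscle, 1 from mice without surgery (day 0) and 1 taken 28 days after surgery that made the hindlimb ischemic (day 28). Per the submitters' processing notes, the tools were Cell Ranger 2.1.1 and STAR, whose version is not stated, with genome build mm10. The deposited values are raw UMI counts per gene and barcode, which the authors did not normalise: every value is a whole number, per the file headers and a check of the values. The lowest barcode total was 3001 UMIs at day 0 and 4175 at day 28, so barcodes under those totals had been left out before deposit. The labels name 3' v1 chemistry, while the barcodes are 16 bases long. The gene table has 27998 Ensembl identifiers without a row for the YFP reporter or Cre. Of these, 27645 were matched to GENCODE M21 on GRCm38 (mm10) for coordinates, and 121 shared a symbol with another identifier and were kept apart.

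Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. This removed 2 barcodes at day 0 and 17 at day 28. Doublets were scored with Scrublet in scanpy 1.11.5, separately per library. Its automatic threshold marked 0.150% and 0.339% of barcodes, under the 0.5% set as a working minimum. The top-scoring cells at the expected rate of 0.8% per 1000 barcodes were therefore left out: 57 at day 0 and 56 at day 28. The kept cells numbered 2610 and 2580. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes and 30 principal components gave a graph of 20 nearest neighbours, which Leiden clustering (leidenalg 0.10.2, resolution 0.8, seed 1) divided into 23 clusters without batch integration.

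Clusters were named "X-like" from 18 marker lists fixed in advance. The score of a list was the mean, over its genes, of the log2 CPM (with 10 CPM added) minus the median of the other clusters. A cluster took the name with the highest score if at least 3 of its markers were found in 10% of the cells and no other class had more markers among the cluster's 10 leading genes by fold. The score also had to be at least 2, or at least 1.5 with an own marker among those 10 genes, and a cluster of low depth needed such a marker too. These numeric thresholds of the naming rule, and the rule that leaves a cluster led by Prss34 or Mcpt8 unnamed, were set after seeing the data. The rule left cluster 3 unnamed for too few detected markers, clusters 2, 8 and 12 because another class had more markers among their leading genes, and cluster 15 for Prss34 and Mcpt8. Genes of the fixed lists that the gene table lacks, at least under those symbols, were Trac, Trbc1, Trbc2, Ighm, Igkc, Iglc2, Leprel1, Ccn1, Ccn2, Vegfd, C1s and Cebpd.

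For each class with at least 50 cells in each library, and for the fibroblast-like cells whatever their number, UMIs were summed over cells and divided by the sum's total and scaled to CPM. Ratios are day 28 over day 0. With 1 library per group no test between conditions is possible, so no p-value or standard error is given. Intervals are exact at 95%: Poisson for a sum, Clopper-Pearson for a share and conditional binomial for a ratio of sums. They cover counting error only, not differences between animals, sorts or library preparations. A gene with 0 UMIs in a library was placed at the floor of 3 UMIs and its ratio given as a bound. A bound that pointed toward the library with 0 UMIs was set to a ratio of 1, a correction made after the values had been seen, because shallow sums had otherwise given undetected genes a direction.

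The gene lists, the comparisons and the rule for naming genes were chosen before the data were examined. In fibroblast-like cells the rule takes the 12 genes with the highest and the 12 with the lowest ratio at a mean of at least 50 CPM. In each other class it takes 6 on each side at a mean of at least 100 CPM, and in each list the 2 highest and 2 lowest members at a mean of at least 10 CPM. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes are left out, and S100a4, Itgam, Pdgfra, Acta2, Col1a1, Vegfa, Mki67, Xist and Ddx3y are always named. A further 6 per side, ranked by the difference from the other clusters' median, were added after seeing the data. A list of 33 was read in a class where at least 5 members reached 10 CPM. Its median log2 ratio was placed as a percentile among 10000 random lists of the same size and of like mean CPM, which describes these 2 libraries and is no test. Members past a ratio of 2 or of 0.5 were counted. A gene is called common to most clusters where its higher value stays under 3 times the 25th percentile of the 11 clusters with 50 cells in each library. For shares of cells with a UMI, every cell was thinned to 3200 UMIs, which left out 225 cells at day 0 and 0 at day 28.

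The scripts were tested on simulated counts with known changes. For the macrophage or monocyte-like comparison (1335 genes), 100% of 2-fold and 100% of 4-fold changes were recovered past the midpoint of their log2 size, and 5% of unchanged lists fell outside percentiles 2.5 to 97.5. For T or NK lymphocyte-like cells (950 genes) the shares were 99% and 100%, and for B lymphocyte-like cells (1306 genes) 100% and 100%. For fibroblast-like cells (2875 genes) 61% of 2-fold and 69% of 4-fold changes were recovered, and 0% of unchanged lists fell outside those percentiles. The simulated counts held counting noise alone, without spread between cells or libraries, so these rates need not carry over to the data. Alternatives covered the cell filter, doublets, clustering resolution, clustering each library alone, thinning, the scaling of the sums (median ratio, and edgeR 4.0.16 TMM factors of 0.903 and 1.11 under R 4.3.3), the weight of each cell, and list floors of 10 or 50 CPM or none. Further alternatives, chosen after seeing the data, were a common floor of 4175 UMIs per cell, clusters shared by both libraries only, leaving out genes that shifted in every cluster, leaving out T or NK lymphocyte-like and dendritic cell-like cells with 3 or more UMIs of 9 precursor genes, and leaving out single fibroblast-like cells or the 3 with 3 or more UMIs of tenocyte markers. Re-clustering of the fibroblast-like cells into states was not run, because there were only 12 and 5 of them. Calculations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Some genes that the naming rules select are not reported here.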

Results

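Single-cell RNA profiles were recorded for cells of mouse hindlimb muscle that carried YFP and lacked CD11b on their surface. The mice were Fsp1-Cre:R26R-EYFP animals, in which Cre driven by the promoter of Fsp1 (the gene S100a4) switches on a lasting YFP label in a cell and its descendants. The library labelled day 0 came from mice without surgery and the library labelled day 28 from mice after hindlimb ischemia surgery, so each group had 1 library and no difference has a replicate check. The day 0 library held 2668 barcodes and 19574562 UMIs, and the day 28 library 2653 barcodes and 38785525 UMIs, beside the 5000 captured cells of the design text. Median depth per barcode was 4844 and 12265 UMIs. After filtering, 2610 and 2580 cells remained, with medians of 4779.5 and 12222 UMIs.

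The first question was whether the sorted cells carried the genes behind the sort. S100a4 (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045, mm10) stood at 229 CPM (95% interval 223 to 236) at day 0 and 232 CPM (227 to 237) at day 28, a ratio of 1.01 (0.976 to 1.05). Its RNA was found in macrophage or monocyte-like cells (1124 and 938 CPM), fibroblast-like cells (469 and 973 CPM), dendritic cell-like cells (424 and 475 CPM) and T or NK lymphocyte-like cells (181 and 512 CPM), and was low in erythroid-like cells (4.41 and 18.2 CPM). A S100a4 UMI was found in 22.6% of day 0 and 46.2% of day 28 cells, or 19.7% and 29.3% after thinning. In erythroid-like cells, taken as a type that should lack it, 5 of 102 and 27 of 127 cells had one at median depths of 9129.5 and 16325 UMIs. The level over all cells did not differ beyond counting error, so no order is read from these shares.

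Itgam, which encodes the CD11b that the gate excluded (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), was found at 6.49 CPM (5.40 to 7.75) and 9.48 CPM (8.52 to 10.5). An Itgam UMI was present in 3.91% and 11.6% of cells, and in 1.76% and 3.10% after thinning. In erythroid-like cells, taken as a type that should lack it, 0 of 102 and 4 of 127 cells had one. The pan-leukocyte gene Ptprc (CD45) stood at 195 CPM at day 0 and 73.3 CPM at day 28, with a UMI in 67.1% and 56.4% of cells, or 50.4% and 23.4% after thinning. Fibroblast-like cells had 0 Ptprc and 0 Itgam UMIs. The stromal genes Pdgfra (0.581 and 0.161 CPM), Acta2 (0.475 and 0.456 CPM) and Col1a1 (4.64 and 2.87 CPM) were near the detection limit over all cells. The proliferation gene Mki67 was higher at day 28 (69.1 and 93.5 CPM), as was Vegfa (2.64 and 5.24 CPM). Both are sums over cell classes whose shares differed between the libraries, so they do not show a difference within a class. The Y-linked Ddx3y stood at 56.8 and 44.9 CPM, and Xist had 0 and 4 UMIs.

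The second question was which cells made up the sort before and after ischemia. Most cells of both libraries fell in named blood-cell classes, and 20.3% of day 0 and 34.8% of day 28 cells were in unnamed clusters. Fibroblast-like cells were 0.460% (0.238% to 0.802%) of day 0 and 0.194% (0.0630% to 0.452%) of day 28 cells, 12 and 5 cells, or 12 and 4 without an endothelial-type cell described further on. T or NK lymphocyte-like cells were 40.8% at day 0 and 3.84% at day 28, a ratio of 0.0941 (0.0758 to 0.116). Macrophage or monocyte-like and dendritic cell-like shares were higher at day 28: macrophage or monocyte-like cells were 8.01% and 17.2%, with a ratio of 2.15 (1.82 to 2.55), and dendritic cell-like cells 9.23% and 14.8%, with a ratio of 1.60 (1.36 to 1.89). Neutrophil-like cells were 2.64% and 11.3%, with a ratio of 4.27 (3.27 to 5.63) that turned in 3 other settings, to as low as 0.314, and was 20.2 with libraries clustered separately. Erythroid-like cells were 3.91% and 4.92%, a ratio of 1.26 (0.963 to 1.65), or 1.61 (1.27 to 2.04) at resolution 0.4. B lymphocyte-like cells were 14.7% and 12.98%, a ratio of 0.885 (0.762 to 1.03) that leaves out cluster 8 with its B cell genes. Under 7 other settings of filter and clustering that ratio was 0.392 to 0.717, with every interval below 1, and the day 0 share went from 12.1% to 35.8%.

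The depth gap and the lowest UMI totals bear on these shares, because lymphocytes hold little RNA. Among cells at or above the lowest day 28 total in both libraries, the ratios were 0.147 for T or NK lymphocyte-like, 1.32 for macrophage or monocyte-like, 1.33 for dendritic cell-like and 2.93 for neutrophil-like cells. The erythroid-like ratio went from 1.26 to 0.796 there, and the B lymphocyte-like ratio from 0.885 to 0.789.

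**Figure D1:**
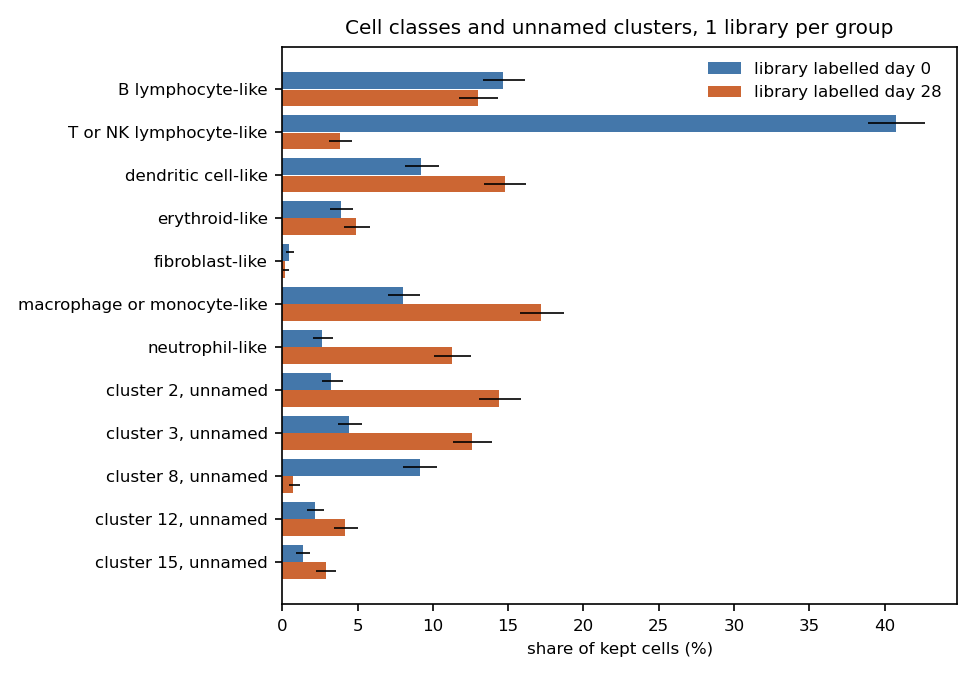
Share of kept cells (%, horizontal axis) in each named class and unnamed cluster for the day 0 and day 28 libraries, with bars for the shares and lines for exact 95% intervals of counting error. T or NK lymphocyte-like cells fill 40.8% of day 0 and 3.84% of day 28, while unnamed clusters 2 and 3 fill 3.26% and 4.44% of day 0 and 14.4% and 12.6% of day 28.

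Of the T or NK lymphocyte-like cells, cluster 1 (led by Dapl1, Cd8b1, Lef1 and Tcf7) had 523 cells at day 0 and 10 at day 28, and cluster 10 (Tnfrsf4, Ctla4, Icos) 218 and 23. Cluster 16, led by the cytokine genes Il17f and Il17a, had 84 and 0, which allows a share of up to 0.143% at day 28. Cluster 6, with Gzma and Klr receptor genes of cytotoxic and NK cells, had 239 and 66. Among B lymphocyte-like cells, clusters 7 (Vpreb3; 130 and 139 cells), 13 (Vpreb1, Dntt, Igll1; 64 and 97) and 14 (Jchain, Sdc1, Mzb1; 26 and 84) made up most of both libraries. Cluster 17 (Cd79b, Ms4a1; 75 and 0) and cluster 18 (Rgs13; 60 and 0) were seen at day 0 only. A cluster mostly of 1 library may be that library rather than a type.

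The naming rule, parts of which were set after seeing the data, kept 5 clusters out of a class, 20.3% of day 0 and 34.8% of day 28 cells together. Cluster 2, led by F13a1 and the granule protease gene Prtn3, was 3.26% and 14.4%. Cluster 3, with Cd34, Myct1, Egfl7 and Angpt1, was 4.44% and 12.6%. Cluster 8, with the B cell genes Ms4a1 and Fcer2a and MHC class II genes, was 9.12% and 0.736%, cluster 12 (Pf4, Car1) 2.15% and 4.19%, and cluster 15 (Prss34, Mcpt8, Fcer1a) 1.34% and 2.87%. The neutrophil-like class joined cluster 5 (Elane, Cebpe, Ms4a3; 2.03% and 11.1%), which has none of the neutrophil markers among its 10 leading genes, to cluster 20 (Ngp, Ltf, Retnlg; 0.613% and 0.194%). The class ratio of 4.27 comes from cluster 5. In 3 alternative settings the class held only 15 or 16 day 0 and 5 day 28 cells, about as many as cluster 20, and the ratio turned, to as low as 0.314.

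The comparison the study is named for is that of fibroblasts. In the 12 day 0 and 5 day 28 fibroblast-like cells, genes of adventitial (Pi16 and Dpp4 type) fibroblasts and of the elastic fibre were lower in the day 28 library, and tendon genes were higher, with 2 day 28 cells and 1 day 0 cell of tendon type. These had 170, 45 and 39 UMIs of tenocyte markers, against 0 to 2 in each of the others. The 11 tendon genes had a median log2 ratio of 1.47 (percentile 100 among matched random lists), 6 of them at least 2-fold higher and 0 at least 2-fold lower. Fmod, a small proteoglycan of tendon collagen (chromosome 1, 134037254 to 134048277), had 10 and 94 UMIs (174 and 3387 CPM) and the cartilage and tendon matrix gene Comp 1 and 14 UMIs, a ratio of 29.0 (4.41 to 1227). Egr1 (417 and 216 CPM) and Tppp3 (1252 and 757 CPM) were lower. The 24 adventitial genes had a median of -0.72 (percentile 0.0), with 10 at least 2-fold lower and 1 at least 2-fold higher. Among them Anxa3 (469 and 72.1 CPM) and the Wnt inhibitor gene Sfrp4 (1147 and 216 CPM) were lowest, and Il33 (86.9 and 360.3 CPM) and Limch1 (122 and 216 CPM) highest. The elastic fibre list of 15 genes had a median of -0.95 (percentile 0.01), led by elastin, Eln, with 24 and 1 UMIs, and Efemp1 with 20 and 2. Ltbp1 (52.1 and 324 CPM) and Mfap4 (226 and 757 CPM) went the other way.

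Single cells carried much of the tendon and lipid differences. Of the 5 day 28 cells, 1 had 2 UMIs of the fibroblast markers and 313 of the endothelial markers, including the 235 UMIs of the fatty acid carrier gene Fabp4 (3 at day 0; chromosome 3, 10204088 to 10208576). The capillary lipid handling list (median 2.04, percentile 100, with Cd36 at 0 and 25 UMIs, Lpl at 574 and 216 CPM and Meox2 at 104 and 108 CPM) rested on that cell, which also held all Cd36 UMIs. The adipogenic list (0.54, percentile 99.4, with Plin2 at 1 and 9 UMIs and Apoe at 1391 and 288 CPM) shares Fabp4 and Cd36 with it. Without it the adventitial median was -0.64, the elastic fibre median -0.66, the tendon median 1.76 and the adipogenic median 0.00 (percentile 48.3). Another day 28 cell held 85 of the 94 Fmod UMIs, and without it the tendon median was 0.78 (percentile 96.6). Without the 3 cells of tendon type, chosen after seeing the data, 11 and 3 cells were left, and 1 of these 3 was the endothelial-type cell. No setting left out that cell together with those of tendon type. Under 5 tendon genes could be measured without the tendon-type cells, and the adventitial and elastic fibre medians were -0.68 and -0.36. Without the Fmod cell alone, with the endothelial-type cell kept, these medians were -0.65 and -0.75. With thinned cells they were -0.53 and -0.29, and with the mean of per-cell CPM -0.50 and -0.41, so the elastic fibre difference is weak, and 1 cell held 72.0% of the Eln UMIs and 63.9% of the Sfrp4 UMIs. Other values that a single cell moves strongly are those of Comp (73.3% of UMIs in 1 cell), Mfap4 (61.8%), Apoe (61.4%), Plin2 (60.0%), Lpl (48.7%), Il33 (40.0%) and Tppp3 (37.6%).

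Among the other genes of the naming rule, the joint lubricant gene Prg4 (1 and 33 UMIs, a ratio of 68.4, 11.4 to 2782), Chad (2 and 44), Angptl7 (3 and 46), Id1 (1 and 7), Inhba (1 and 7), Ccl5 (2 and 13) and Ccdc3 (3 and 18) were higher at day 28, with 55.9% (Prg4) to 93.9% (Angptl7) of the UMIs of each in 1 cell. Thinned, the log2 ratio of Inhba was 1.14 instead of 3.86, that of Ccl5 1.72 instead of 3.75 and that of Plin2 1.87 instead of 4.22. Lower were the protease inhibitor gene Serpine2 (87 and 2 UMIs, found in 10 of 12 and 1 of 5 cells, 21.0-fold lower, 5.64 to 176, 58.4% of the UMIs in 1 cell), Tmem176b (50 and 2), the eosinophil chemokine gene Ccl11 (24 and 1), Tgfbi (19 and 1), Uap1 (17 and 1), Usmg5 (21 and 1), Tmem14c (17 and 1) and Tmem258 (17 and 1), the last 3 at levels common to most clusters. Thinned, the log2 ratio of Usmg5 was -0.45 instead of -3.34, that of Tmem258 -0.74 and that of Tmem14c -2.32. Haptoglobin, Hp (142 and 0 UMIs), was at least 22.8-fold lower and Ccl2 (82 and 0) at least 13.2-fold lower, each from 1 day 0 cell and not the same one. Cd74 (63 and 1 UMIs) was lower in every cell class compared. A single cell also held 75% of the UMIs of Cd74, 67.3% of Tmem176b, 55.0% of Tgfbi, 48.0% of Ccl11, 55.9% of Gas6, 44.9% of Gpx3, 40.9% of Col1a1 and 38.6% of Col1a2. Col1a1 had 85 and 96 UMIs (1478 and 3459 CPM), a ratio of 2.34 (1.73 to 3.17), and Col1a2 2173 and 6413 CPM. Bmp1 (209 and 36.0 CPM) and Col5a1 (191 and 36.0 CPM) were lower, and the fibrillar collagen list as a whole had a median of -0.21 (percentile 1.64), but 0.02 (percentile 40.6) without the endothelial-type cell. The median was -0.58 (percentile 0.08) without the Fmod cell and -0.36 (percentile 0.27) without the 3 cells of tendon type. The endothelial-type cell was kept in both of these settings, so the collagen median depends on which cells are kept. S100a4 had 27 and 27 UMIs (469 and 973 CPM), Pdgfra 11 and 3, Vegfa 1 and 1, and Acta2 and Mki67 0 and 0. The insulin-like growth factor gene Igf1 (38 and 5 UMIs) and Gas6 (32 and 2) were the lowest of the 27 growth factor genes. Their median was 0.00 (percentile 25.1), with 4 at least 2-fold higher and 7 at least 2-fold lower. In these shallow sums a list median of 0.00 is the value of genes whose bound was set to a ratio of 1, so it does not show that a list was unchanged. The matricellular list (0.00, percentile 30.6), the myofibroblast list (0.05, percentile 45.9), the hypoxia list (0.47, percentile 87.8) and the interferon list (0.47, percentile 84.1) also lay within the middle 95% of random lists. Of 33 lists, 3 lay above that range and 7 below, and those led with here were chosen after their values were seen. The other 4 low lists were immediate early and dissociation stress genes, called immediate early genes here (-0.42, percentile 0.54; Fosb at 330.3 and 72.1 CPM), antioxidant genes (-0.12, percentile 1.92; Gpx3 at 8083 and 2198 CPM), S100 ligands (-0.67, percentile 1.13; S100a11 at 2190.2 and 901 CPM) and arterial genes (-0.18, percentile 2.44; Fbln5 at 243 and 72.1 CPM). Without the endothelial-type cell the S100 ligand median was -0.42 (percentile 4.64), within the middle 95%, and the arterial list had under 5 measured genes, while immediate early (-0.52, percentile 0.15) and antioxidant genes (-0.14, percentile 0.89) stayed low. Without the 3 cells of tendon type the S100 ligand median was -1.12 (percentile 0.165) and the interferon median 1.05 (percentile 99.3), both outside the middle 95%. The endothelial-type cell was 1 of the 3 day 28 cells left there, so these 2 values are not those of fibroblasts alone.

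**Figure D2:**
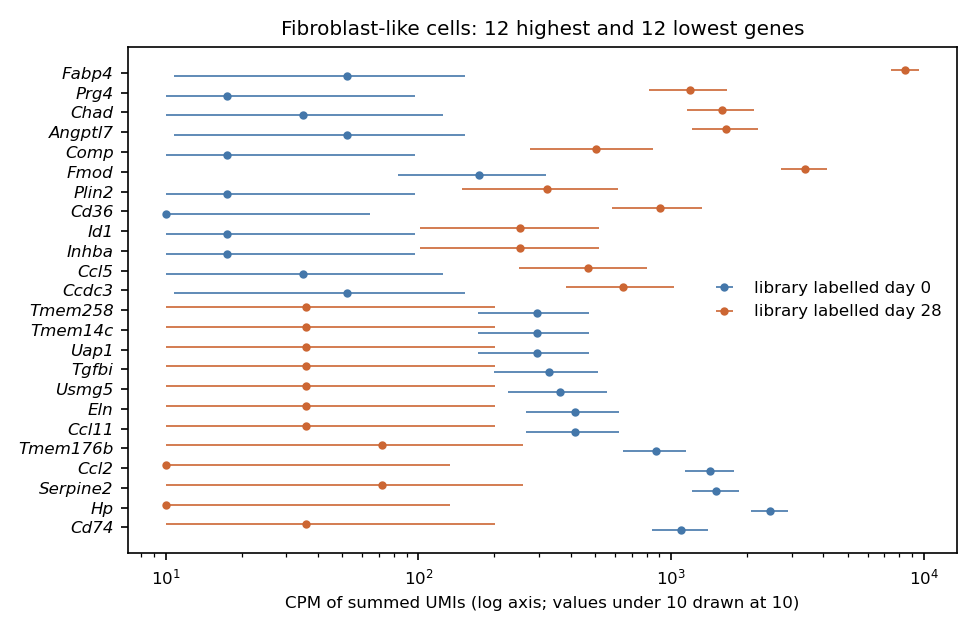
CPM of the summed UMIs (horizontal log axis, values under 10 drawn at 10) of the 12 highest and 12 lowest genes by ratio in fibroblast-like cells, 12 cells at day 0 and 5 at day 28, with lines for exact 95% Poisson intervals. Fabp4 stands at 52.1 and 8466 CPM, nearly all from 1 cell, and Serpine2 at 1512 and 72.1 CPM.

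T or NK lymphocyte-like cells of day 28 carried more cell cycle RNA, and many of them also carried genes of blood-cell precursors. The cell cycle list had a median log2 ratio of 2.01 against -0.02 for all genes, with 22 of 24 members at least 2-fold higher and 0 at least 2-fold lower (percentile 100). Ccna2, which drives S phase and mitosis, stood at 9.70 and 112 CPM, the kinetochore gene Cenpf at 6.75 and 59.6 CPM, and Mki67 at 10.97 and 74.9 CPM, while Tubb5 (658 and 1165 CPM) and Mcm2 (18.8 and 36.7 CPM) moved least. Cluster 6 alone, the sole T or NK cluster with 50 cells in each library, gave a median of 1.46 (percentile 100). Of the class, 18 of 1064 day 0 cells and 49 of 99 day 28 cells had 3 or more UMIs of 9 precursor genes, at unequal depth, and in thinned cluster 6 cells the shares were 0.472% and 12.1%. Without these cells, an alternative chosen after seeing the data, the cell cycle median was 0.92 in the class, with 9 of 21 members at least 2-fold higher, and 0.21 in cluster 6. The cell cycle difference was smaller without these cells. The cut was made before thinning, and deeper cells reach 3 such UMIs more readily. Free RNA of the precursor genes was not told apart from the cells' own RNA, so what these cells are was not settled. Gzma, a granule protease of cytotoxic cells, was higher (31.2 and 312 CPM, and 132 and 502 CPM within cluster 6), although 1 cell held 32.9% of its UMIs there. Also higher were Lgals1 (539 and 1718 CPM), Lgals3 (50.2 and 164 CPM), Itgb1 (65.8 and 179 CPM), Anxa2 (86.1 and 274 CPM) and S100a4 (181 and 512 CPM), and the S100 ligand list had a median of 0.67 (percentile 99.8), but 0.16 (percentile 89.9) in cluster 6. Ccr7 (199 and 35.2 CPM), Igfbp4 (171 and 35.2 CPM), Dapl1 (324 and 36.7 CPM) and Cd8b1 (504 and 110.1 CPM) were lower. Cluster 1, which Dapl1 and Cd8b1 lead, held 523 of 1064 class cells at day 0 and 10 of 99 at day 28, and cluster 6 held 239 and 66. The class values of the genes from Lgals1 to Cd8b1 may therefore reflect this makeup, and levels within cluster 1 were not compared.

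Within cluster 6 the T cell receptor component Cd3e stood at 389.8 and 98.8 CPM, Cd3d at 853 and 569 CPM and Ms4a4b at 1004 and 304 CPM. The ER protein folding list was higher in the class (0.55, percentile 100; Hsp90b1 at 75.7 and 209 CPM, Creld2 at 15.2 and 41.3 CPM, Dnajb9 at 69.0 and 38.2 CPM), as was the hypoxia and glycolysis list (0.28, percentile 98.5; Tpi1 at 60.1 and 151 CPM, Pdk1 at 64.1 and 22.9 CPM). In cluster 6 the hypoxia list was not higher (-0.10, percentile 43.9), while the ER folding list was (0.21, percentile 98.8). The interferon list was lower (-0.42, percentile 1.55; Gbp2 at 20.04 and 9.17 CPM, Ifitm3 at 7.17 and 21.4 CPM), but in cluster 6 alone its median was 0.31 (percentile 98.4). The adventitial list held only 5 measured genes here (-1.55, percentile 0.02), with Dpp4, also the lymphocyte surface protease CD26, at 22.2 and 4.59 CPM and Cd55 at 42.8 and 13.8 CPM. MHC class II genes and Cd79a (397 and 68.8 CPM), with H2-Ab1 at 585 and 65.7 CPM and H2-Eb1 at 451 and 73.4 CPM, were lower in the class, where clusters 10 and 16, which hold B cell RNA, are nearly all day 0. Jchain (21.7 and 254 CPM), Ube2c (27.6 and 219 CPM), Hmgb2 (385 and 1462 CPM) and Stmn1 (90.1 and 312 CPM) were at levels common to most clusters.

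**Figure D3:**
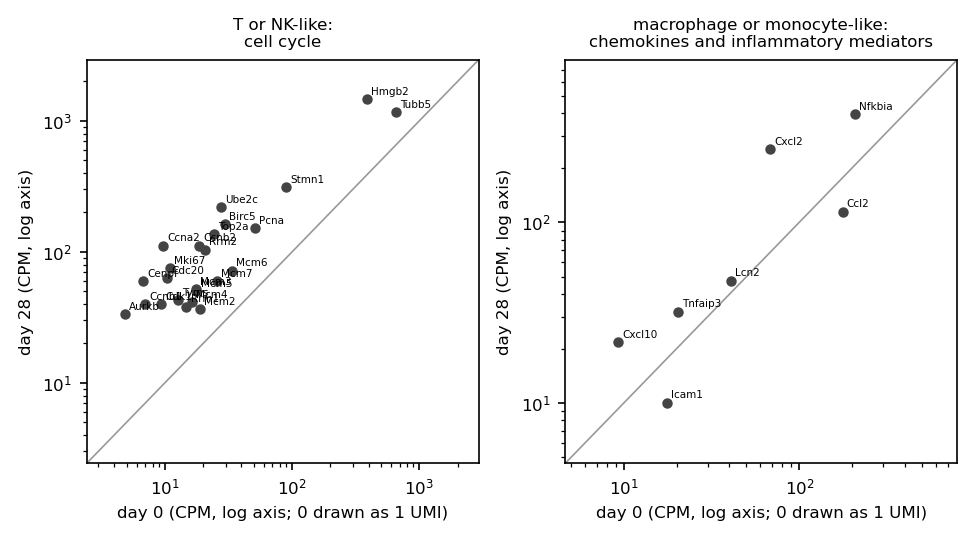
CPM at day 28 (vertical log axis) against CPM at day 0 (horizontal log axis) for the measured members of the cell cycle list in T or NK lymphocyte-like cells (left) and of the chemokine list in macrophage or monocyte-like cells (right), 1 point per gene, with the line of equality. Every cell cycle gene lies above the line, from Tubb5 at 658 and 1165 CPM to Ccna2 at 9.70 and 112 CPM, and Ccl2 and Icam1 lie below it.

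Macrophage or monocyte-like cells, all in cluster 0, were compared for inflammatory output. The chemokine and inflammatory list was higher in the day 28 library, with a median log2 ratio of 0.66 over 7 members against -0.13 for all genes (percentile 100), 2 of them at least 2-fold higher and 0 at least 2-fold lower. Cxcl2, which attracts neutrophils (chromosome 5, 90903871 to 90905938), stood at 68.3 and 254 CPM, a ratio with an interval of 3.15 to 4.41, and the interferon-induced Cxcl10 at 9.26 and 21.8 CPM. Ccl4 (126 and 192 CPM) was also higher, and Nfkbia (208 and 396 CPM) was higher at a level common to most clusters. The monocyte attractant Ccl2 (176 and 115 CPM) and the adhesion gene Icam1 (17.6 and 10.1 CPM) were lower. S100a8, an alarmin of neutrophils and monocytes, stood at 156 and 268 CPM. The lipopolysaccharide co-receptor gene Cd14 (148 and 61.9 CPM), Ifitm6 (202 and 88.4 CPM) and lysozyme, Lyz2 (14675 and 8674 CPM), were lower. The S100 ligand list had a median of -0.40 (percentile 1.11; S100a11 at 1119 and 745 CPM, Anxa2 at 949 and 668 CPM). The median log2 ratio that median-ratio scaling subtracts was -0.12 in this class, and the chemokine median relative to it was 0.78.

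Dendritic cell-like cells consisted of cluster 4 (Cd209a, Batf3; 109 and 244 cells), cluster 9 (Siglech, Ccr9, genes of plasmacytoid cells; 125 and 131 cells) and cluster 22 (Fscn1; 7 and 6 cells). Their chemokine list was higher (0.47 over 6 members against -0.12 for all genes, percentile 99.9; Ccl2 at 6.99 and 17.2 CPM, Cxcl2 at 15.3 and 25.7 CPM, Cxcl16 at 56.6 and 36.4 CPM). So was the cell cycle list (0.42, percentile 100, with 0 of 26 members past 2-fold; Ube2c at 189 and 327 CPM, Mcm2 at 53.4 and 36.4 CPM). At the common UMI floor the cell cycle median was 0.20, in cluster 4 alone 0.11 and in cluster 9 alone 0.63. In thinned cluster 9 cells the share with 3 or more UMIs of precursor genes was 7.26% and 25.2%. All cells at 3 or more such UMIs before thinning were then left out, an alternative chosen after seeing the data. This left 184 and 113 class cells with a median of -0.0763, so the class difference was not kept, while the median of cluster 9 was 0.71. In cluster 4, 70 of 109 and 53 of 244 cells were left, with a median of -0.27. The cluster 4 gene values below include its cells with precursor genes, and how far these account for them was not settled. In plasmacytoid cluster 9, the chemokine gene Ccl4 was higher, at 2355 and 6145 CPM, with an interval of the ratio of 2.45 to 2.78. The kinase gene Map3k8 (73.8 and 160 CPM), the activation marker Cd69 (93.2 and 168 CPM) and Plaur (165 and 270.5 CPM) were also higher. In cluster 4 the transcription factor genes Klf6 (61.4 and 178 CPM) and Id2 (163 and 302 CPM) and the hydrolase gene Naaa (110.0 and 194 CPM) were higher. The lectin receptor gene Cd209a (260.2 and 112 CPM), Cd7 (727 and 312 CPM) and Gsn (152 and 68.8 CPM) were lower. The lysosomal genes Grn (806 and 329.9 CPM) and Ctsl (585 and 229 CPM) and the receptor gene Klrd1 (217 and 80.0 CPM) were lower in the class as a whole. Ctsl leads cluster 9, which held 125 of 241 class cells at day 0 and 131 of 381 at day 28, while Grn was also lower within cluster 9 (1352 and 507 CPM). Jchain (18.4 and 647 CPM) was higher, with 42.0% of its UMIs in 1 cell.

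B lymphocyte-like cells of day 28 had higher medians for the ER folding and antioxidant lists, which were below 0 in the shared clusters pooled. The ER protein folding list had a median of 0.47 against -0.14 for all genes (percentile 100; Xbp1, which controls the secretory programme of plasma cells, at 177 and 423 CPM, P4hb at 76.7 and 174 CPM). The antioxidant list had a median of 0.35 (percentile 100). It was led by the metallothioneins Mt1 (109 and 592 CPM) and Mt2 (40.5 and 293 CPM), with Prdx1 at 734 and 419 CPM and Cat at 65.6 and 44.8 CPM. In clusters 7 and 13 pooled, which have 50 cells in each library, these medians were -0.13 and -0.0104. In cluster 7 alone they were -0.03 (percentile 97.2) and 0.07 (percentile 98.8) against -0.23 for all genes, and in cluster 13 -0.13 (percentile 39.5) and 0.05 (percentile 86.1). Cluster 14 (Jchain, Sdc1, Mzb1), left out of that pool, held 26 of 383 class cells at day 0 and 84 of 335 at day 28. Levels within it were not compared, so how far the makeup of the class accounts for both medians was not settled. Ms4a1 (CD20; 399 and 37.2 CPM), the class II chaperone gene H2-DMb2 (241 and 31.9 CPM), Fcmr (192 and 25.8 CPM), Ltb (234 and 30.4 CPM) and Apoe (479 and 52.7 CPM) were lower, and clusters 17 and 18 had 0 cells at day 28. Interferon genes were lower too (-0.57, percentile 0.855; Irf1 at 41.3 and 23.1 CPM), with Ifitm3 (23.5 and 61.2 CPM) and Bst2 (58.4 and 109 CPM) the other way. Of 9 members 0 were at least 2-fold lower and 1 at least 2-fold higher, and in clusters 7 and 13 the interferon list lay within the middle 95% (-0.52, percentile 7.27, and -0.36, percentile 10.6). The granule genes Prtn3 (15.9 and 676 CPM), Elane (33.4 and 947 CPM), Mpo (27.8 and 464 CPM), Ctsg (11.1 and 335 CPM), S100a8 (25.4 and 643 CPM) and S100a9 (22.3 and 299.5 CPM) headed the class, with 15.8% to 22.6% of the UMIs of each in 1 cell. Prtn3 and Elane were also higher in erythroid-like cells. Whether free RNA or misplaced cells account for the granule genes in B lymphocyte-like cells was not tested.

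Neutrophil-like cells held 53 and 286 cells of cluster 5 and 16 and 5 of cluster 20, so the mature granule genes that define cluster 20, Retnlg (745 and 15.8 CPM), Ltf (532 and 30.5 CPM), Ngp (3543 and 348 CPM) and Lcn2 (1074 and 141 CPM), and Ifitm6 (195 and 14.0 CPM), were lower in the class. Within cluster 5 the antimicrobial peptide gene Camp was higher (65.6 and 295 CPM, 22.8% of its UMIs in 1 cell), and Mpo (7857 and 4161 CPM), Elane (15153 and 9647 CPM) and Alas1 (359 and 114 CPM) were lower. Smc4 (141 and 254 CPM), Ube2c (104 and 216 CPM) and B4galt6 (78.2 and 135 CPM) were higher in the class, the first 2 at levels common to most clusters. The chemokine list was higher (0.30, percentile 98.3), with Cxcl10 at 0 and 141 UMIs, at least 9.13-fold higher, while 1 of the 6 members (Lcn2, 1074 and 141 CPM) was at least 2-fold lower. The ER folding list was higher (0.25, percentile 99.98; Hsp90b1 at 261 and 416 CPM), and the oxidative phosphorylation list was lower (-0.21, percentile 0.535; Uqcrb at 524 and 284 CPM), with 0 of 20 and 0 of 33 members past 2-fold. Also low were immediate early genes (-0.27, percentile 1.43, with 3 of 23 at least 2-fold lower; Fos at 119 and 58.7 CPM), adipogenic genes (-0.48, percentile 0.67, with 0 of 7 past 2-fold; Plin2 at 61.6 and 35.3 CPM) and the parenchymal fibroblast list (-0.46, percentile 2.27, with 0 of 5 past 2-fold). In cluster 5 alone the ER folding (0.17, percentile 99.9) and oxidative phosphorylation (-0.28, percentile 0.06) lists kept their place. The chemokine (0.06, percentile 78.7), immediate early (-0.20, percentile 15.1), adipogenic (-0.37, percentile 4.89) and parenchymal (-0.08, percentile 52.8) lists there lay within the middle 95%.

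Erythroid-like cells, cluster 11, differed in stress and growth genes. The immediate early list was lower at day 28, with a median of -0.46 against 0.10 for all genes (percentile 0.0; Junb at 162 and 63.0 CPM, Dusp1 at 168 and 67.3 CPM). Of its 20 members 3 were at least 2-fold lower and 1 at least 2-fold higher. As it also holds dissociation stress genes, an effect of cell handling cannot be told apart. Cell cycle genes were lower too (-0.36, percentile 0.0, with 0 of 26 past 2-fold; Tyms at 281 and 158 CPM, Rrm2 at 1403 and 886 CPM). Mt1 (48.5 and 158 CPM) and the chaperone genes Hspe1 (239 and 539 CPM) and Hsp90ab1 (896 and 1804 CPM) were higher, the chaperones at levels common to most clusters. The hypoxia and glycolysis list was higher (0.50, percentile 99.9; Gpi1 at 45.0 and 85.1 CPM, Eno1 at 66.1 and 18.2 CPM), with 0 of 12 members at least 2-fold higher and 1 at least 2-fold lower. The interferon list was lower (-0.30, percentile 0.56; Isg15 at 56.4 and 16.1 CPM, Rsad2 at 48.5 and 14.3 CPM), with 2 of 14 members at least 2-fold lower and 0 at least 2-fold higher. The S100 ligand list had a median of 1.15 (percentile 100), led by S100a4 at 5 and 42 UMIs and S100a11 at 13 and 71. Prtn3 (18.5 and 192 CPM), Elane (24.7 and 213 CPM) and Plac8 (42.3 and 250 CPM) were also higher, and all 5 genes were at levels common to most clusters. There were 39.8% of the Elane UMIs in 1 cell.

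**Figure D4:**
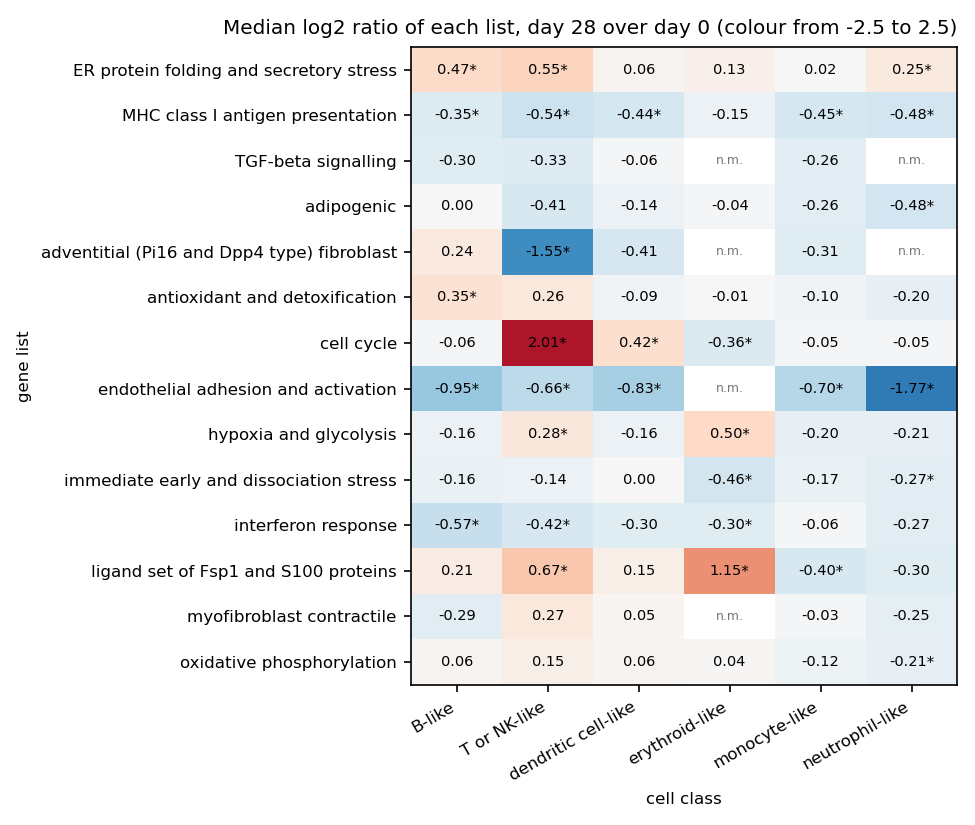
Median log2 ratio, day 28 over day 0, of gene lists (vertical axis) in 6 cell classes (horizontal axis), with each median printed in its cell, * for a median outside the middle 95% of random lists and n.m. for fewer than 5 measured members. The cell cycle list stands at 2.01 in T or NK lymphocyte-like cells and -0.36 in erythroid-like cells, and the MHC class I list is below 0 in all 6 classes.

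The MHC class I antigen presentation list was lower in 5 leukocyte classes, though only 1 or 2 of its 12 or 13 members per class were at least 2-fold lower, with medians of -0.35 in B lymphocyte-like (percentile 2.18), -0.54 in T or NK lymphocyte-like (0.07), -0.44 in dendritic cell-like (0.08), -0.45 in macrophage or monocyte-like (0.12) and -0.48 in neutrophil-like cells (0.04), while fibroblast-like cells had 0.68 (93.7). Within the dendritic class the median was -0.58 in cluster 9 (percentile 0.01) and -0.13 in cluster 4 (percentile 25.2), the same as all genes there, and in unnamed cluster 2 it was -0.24 (percentile 18.7). H2-Q4 and H2-T23 led the list in T or NK lymphocyte-like cells (157 and 56.6 CPM, 75.7 and 45.9 CPM), and as H2 genes resemble each other closely their counts are uncertain. The endothelial adhesion list was lower in 5 classes (-0.95, -0.66, -0.83, -0.70 and -1.77 in B, T or NK, dendritic, macrophage or monocyte and neutrophil-like cells; percentiles 0.02, 0.45, 0.005, 0.02 and 0.0), though not in neutrophil-like cluster 5 (-0.43, percentile 5.17) or dendritic cluster 4 (-0.26, percentile 16.4). In these classes its lowest members included Cd74, the MHC class II invariant chain, or Klf2, a transcription factor of quiescent lymphocytes and endothelium. Some genes shifted in the same direction by more than 0.5 log2 in every cluster that measured them. Of 2828 genes measured in at least 8 of 11 clusters, 34 were lower in all and 17 higher in all at day 28. The lower ones included Hist1h2ap (median log2 -4.85), Gstp1 (-4.90), Cd74 (-2.85), Cd79a (-2.31), Eno1 (-1.82), Klf2 (-1.33), Serinc3 (-1.02) and Urod (-0.99), and the higher ones Rnaset2b (1.37), Rnaset2a (1.28), Rpl29 (1.14) and Wdr89 (0.81).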

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

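The tests on bone marrow cells, chance doublets, B cell RNA in T cell droplets and free B cell RNA were chosen after the results they measure were seen, the bound for stuck cells was read with its spread after its result, and the bone marrow gene set was shortened by 1 gene after its result.

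In T or NK lymphocyte-like cells the cell cycle list had a median log2 ratio of 2.01 and in erythroid-like cells of -0.36, opposite directions that differ by 2.38. The S100 ligand list stood at 1.15 in erythroid-like and -0.40 in macrophage or monocyte-like cells, also opposite, a difference of 1.55. The erythroid list was led by S100a4 (5 and 42 UMIs) and S100a11 (13 and 71), both at levels common to most clusters. Without T or NK lymphocyte-like cells that carry precursor genes the cell cycle median was 0.92, chosen after seeing the data. Neither difference was tested, as each group had 1 library.

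A sort for a fibroblast label gave 12 and 5 fibroblast-like cells, 1 of the 5 with endothelial markers and only 1 UMI of the matrix genes named next. The filters and clustering here are argued against as the cause, since 2 barcodes outside the cluster had 3 or more UMIs of Col1a1, Col1a2, Col3a1 and Dcn. Fibroblasts under the submitters' UMI minimum cannot be told apart from fibroblasts absent from the sort, as the fibroblast-like cells lay at 1.48 times the lowest total at day 0 and 1.22 at day 28 and barcodes below it were not analysed here. A candidate explanation is blood-forming cells of the bone marrow in the suspension. Of thinned cells, 22.98% at day 0 and 69.3% at day 28 had 3 or more UMIs of 9 precursor genes (Mpo, Elane, Prtn3, Ctsg, Dntt, Vpreb1, Igll1, Kit and Rhd). In T cell cluster 1 these were 0 of 411 cells at day 0 and 0 of 10 at day 28, which allows up to 30.8%. The day 28 background is therefore poorly known. The CD11b gate would remove part of such cells, and the same measure was 0.472% at day 0 and 12.1% at day 28 in T or NK cluster 6. Label activity in blood cells, which S100a4 at 1124 CPM in macrophage or monocyte-like cells would allow, an exchange of these libraries with another sort, and an effect of ischemia were not tested.

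T cell clusters 10 and 16, nearly all from day 0, also held B cell RNA: 218 of 302 cells had 3 or more UMIs of Cd79a, Cd79b and Ms4a1. Chance doublets are argued against, as these cells were 3.82 times the 57 doublets expected in the library, and so is free RNA, as the share in cluster 1 was 0.00744 of that in cluster 10 (0.574% and 77.1%). RNA of B cells in the droplets of T cells may account for it, by a route that was not settled. In cluster 10, 68 genes of B cell cluster 8 stood at a median 36.4% of their cluster 8 level, with an upper to lower quartile ratio of 1.29. Cd79a stood at 35.7%, Ms4a1 at 30.3% and Cd74 at 31.9%. Whole B cells stuck to T cells would leave an even fraction too, so this measure does not separate the routes. Whether whole B cells were stuck to T cells cannot be told, because cells with B cell UMIs had 1.09996 times (0.869 to 1.20) the UMI total of those without, on the bound of 1.1 set beforehand and within its spread. Transfer of B cell membrane and RNA in the tissue, and any role of ischemia, were not tested.

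The 51 genes shifted in every cluster span unrelated cell types. Reads shared with near-identical genes may account for part, since 22 of 51 (43.1%) had at least 50% of the words of their transcript ends in another gene, 6.47 times the 6.67% of unshifted genes of like level, among them Hist1h2ap, Gstp1, Eno1, Rpl29 and Rnaset2a. Free RNA that differs between the libraries cannot be told apart from other causes. About the same level in every cluster was seen for 21.6% of the genes (11 of 51, interval 11.3% to 35.3%). That interval spans the 20% set beforehand as the level that would argue against it. A gene that some cluster expresses itself cannot meet this measure. It therefore cannot decide for genes such as Cd74 and Cd79a, whose highest cluster was 36.1 and 37.7 times the lowest. Cd74, Cd79a, Klf2, Ctss and Serinc3 share no words with other genes, so the shared-read explanation does not reach them. The labels give the same tools and build for both libraries, but unequal read lengths or annotation, a difference between the 2 preparations and an effect of ischemia on all cells stay open and were not tested.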

How the results depend on the processing

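Settings based on the common UMI floor, on shared clusters, on genes that shift everywhere, on precursor genes and on single fibroblast-like cells were chosen after seeing the data. No paired analysis was possible because each group has 1 library. States of fibroblast-like cells were not run, with 12 and 5 cells, and without the Fabp4 cell the capillary lipid list gave no value, as under 5 members were left, nor did the tendon list without the 3 cells of tendon type. Clustering each library alone named 131 day 0 and 0 day 28 cells fibroblast-like (5.02% and 0%), so no ratio was formed. As only 12 day 0 barcodes held 3 or more UMIs of 4 matrix genes, that name was an error of the naming rule. Counting intervals of 12 and 5 cells allow share ratios from 0.116 to 1.29, so a difference in fibroblast share was not detectable at this depth. Of 56 alternative share ratios 36 stayed within the main interval, 17 moved and 3 reversed; of 113 list medians 92, 17 and 4; of 216 fibroblast-like gene values 193, 16 and 7; of 72 gene values in other classes 70, 2 and 0. Of the settings for fibroblast-like genes and lists, the strict filter, no filter and doublets kept each gave 12 and 5 cells, as in the main analysis. The tendon median was 1.47 in all 3. Fibroblast-like values could hardly differ under these settings, so the counts of those that stayed overstate their stability. For the moved and reversed values the cause was not tested, apart from those whose construction shows it.

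The B lymphocyte-like share ratio, 0.885, became 0.572 without a cell filter, 0.646 with the strict filter, 0.510 with doublets kept, 0.597 and 0.626 at resolutions 0.4 and 1.5, 0.717 with libraries clustered separately and 0.392 thinned. The neutrophil-like ratio, 4.27, reversed to 0.314 without a cell filter, 0.337 with doublets kept and 0.316 at resolution 0.4, where 15 or 16 day 0 and 5 day 28 cells kept the name, about as many as cluster 20 holds, and was 20.2 with libraries clustered separately. The T or NK lymphocyte-like ratio was 0.133 with the strict filter and 0.122 with separate clustering, and the macrophage or monocyte-like ratio 1.58 with separate clustering and 1.78 thinned. At the common floor the ratios were 0.147 (T or NK), 1.33 (dendritic), 0.796 (erythroid), 1.32 (macrophage or monocyte) and 2.93 (neutrophil), as the floor removes day 0 cells only. Thinning took the ratio of the shares of cells with a UMI to 1.49 for S100a4, 1.76 for Itgam and 0.463 for Ptprc.

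In fibroblast-like cells, thinning gave 1.51 for the capillary lipid list, and the edgeR TMM factor -1.02 for the adventitial and -1.24 for the elastic fibre list. With thinned cells and with the mean of per-cell CPM the adventitial and elastic fibre medians were smaller in size than in the main analysis, as given above. In shared clusters only, cell cycle and MHC class I medians of T or NK lymphocyte-like cells were 1.46 and -0.80, dendritic chemokine and MHC class I medians 0.97 and -0.35, and the B lymphocyte-like MHC class I median -0.68, while the B lymphocyte-like ER folding and antioxidant medians reversed to -0.13 and -0.0104, with clusters 14, 17, 18 and 19 left out. Without cells that carry precursor genes the T or NK lymphocyte-like cell cycle median was 0.92, or 0.21 in the shared cluster, where the MHC class I median was -0.66. The dendritic cell cycle median reversed to -0.0763, or -0.13 in shared clusters, where the chemokine and MHC class I medians were 0.85 and -0.30. The common floor gave cell cycle medians of 1.40 (T or NK) and 0.20 (dendritic), and median-ratio scaling -0.42 for erythroid cell cycle and 0.32 for neutrophil-like ER folding. Over all kept cells, where fibroblast-like cells supply few of the UMIs, 7 fibroblast-like gene ratios reversed: Cd36 to -0.25, Ccl5 to -2.26, Hp to 0.37, Serpine2 to 0.31, Tmem176b to 0.0862, Tgfbi to 0.33 and Uap1 to 0.0143. The median log2 ratio that scaling subtracts passed 0.1 in size in cluster 0 (-0.12), cluster 2 (-0.15), cluster 3 (-0.14), cluster 5 (-0.10), cluster 7 (-0.21), cluster 9 (-0.12) and cluster 12 (-0.14).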

Other observations

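Unnamed clusters 2, 3 and 12 held genes of blood-cell precursors, and their contents differed between the libraries as well as their shares. In cluster 2 the granule enzyme genes Mpo (4086 and 1787 CPM), Elane (5153 and 2827 CPM) and Ctsg (2468 and 1328 CPM) were lower at day 28, as was the monocyte surface gene Ly6c2 (2845 and 1283 CPM). No list of granule genes was fixed, so these are single genes. Prtn3, a neighbouring protease gene, stood at 3817 and 3568 CPM, and the long noncoding RNA gene Neat1 at 176 and 271 CPM. In cluster 3, which carries the stem and progenitor gene Cd34, immediate early genes were lower (median log2 ratio -0.52 against -0.20 for all genes, percentile 0.0), with Junb at 889.5 and 348.5 CPM and Fos at 1010 and 428 CPM, and Car2 was at 311 and 134 CPM. Ms4a3, a gene of granulocyte and monocyte precursors, was higher (142 and 225 CPM), as was the chaperone gene Calr (831 and 1162 CPM). The immediate early list also holds dissociation stress genes, so an effect of cell handling cannot be told apart here or in the clusters below.

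In cluster 12, with the platelet chemokine gene Pf4 and Car1, the immediate early list had its lowest median of the clusters read (-0.96, percentile 0.0, with 11 of 25 members at least 2-fold lower), led by Fos (383 and 62.4 CPM) and Dusp1 (164 and 35.2 CPM), with Ier2 (423 and 102 CPM) and Egr1 (213 and 67.6 CPM) also lower; Dusp1 and Ier2 were at levels common to most clusters. Pf4 itself was lower (2285 and 965 CPM) and the haem synthesis gene Cpox higher (114 and 197 CPM). The 2 pre-B type clusters went apart on the cell cycle list: its median was -0.50 in cluster 7 (percentile 0.01) and 0.27 in cluster 13 (percentile 100), where Ube2c was at 290.3 and 618 CPM and Birc5 at 226 and 407 CPM, the latter at a level common to most clusters. Immediate early genes were lower in both, at -0.53 and -0.57 (percentiles 0.08 and 0.0). In plasmacytoid cluster 9 the median was 0.14 (percentile 99.5), with 2 of 25 members at least 2-fold higher and 1 at least 2-fold lower. Cell cycle genes in cluster 9 had a median of 0.63 (percentile 99.98), with 5 of 14 members at least 2-fold higher. Precursor genes were found in 7.26% and 25.2% of thinned cluster 9 cells, and without all cells at 3 or more such UMIs before thinning, chosen after seeing the data, 107 and 58 were left and the cell cycle median was 0.71. The Klf6, Naaa and Cd69 differences given for dendritic clusters, and these cluster values, describe 1 library per group and were read after the data were seen.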
